A study of Arabidopsis thaliana with 9 samples.

How the data were processed

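Total RNA was sequenced from hand-dissected oscillation zones of Arabidopsis thaliana roots, with 3 samples each of a Col0 control, the potent line and the arf7 line (9 samples). Groups were taken from the sample titles. Per the labels' protocols, expression of DR5::Luciferase was followed, the zones were dissected at 7 dpi and frozen, and libraries were made by a cited protocol (Picelli and co-workers) for full-length cDNA from very small RNA inputs. The submitters' processing notes name Bowtie2, Bowtie, TopHat2, TopHat, Cufflinks, Cuffdiff and the genome build TAIR10, without versions, roles or order. The annotation release and the settings are not given in the sources used here.

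The deposited expression table holds 31124 loci with 1 value per genotype, so the authors had already combined the 3 samples of each group. Its header gives no unit. The values were taken as FPKM (fragments scaled by transcript length and by the total of mapped fragments) because the submitters' processing notes name Cufflinks and Cuffdiff, and because they are not whole numbers and sum to 905924 in the control, 879820 in potent and 850089 in arf7. The depth of the samples is unknown, so no interval or detection limit was computed. An FPKM divides by transcript length and by the total, so a few very abundant transcripts can lower all others in a genotype. The 100 highest loci took 20.6% of the sum in the control, 23.2% in potent and 22.9% in arf7. Some abundant loci are at exactly 0 in a single genotype: 12 loci at 0 in the control, 12 at 0 in potent and 11 at 0 in arf7 have at least 20 FPKM in both of the others. A 0 can therefore be a failed estimate, and such loci are described as listed at 0, with no fold.

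The authors' deposited comparison table has 2577 entries, each with a q-value and a log2 fold change of a mutant against the control. Every numeric log2 fold change in the authors' deposited table equals the log2 ratio of the deposited FPKM within 0.0001, and 490 entries hold the text >10 or <-10 where a genotype is at 0. Its q-values run from 0.00145 to 0.00945. The design fixed before the data were examined foresaw this case: without values per sample no test was run here, and the authors' listing stands as deposited. A gene is said to have risen or fallen only where the authors' deposited table lists it, and a gene outside that table is described by its values. Absence from the table is not evidence of no change, since the table holds no locus that changed by less than 1.14 on the log2 scale and omits pairs of values described in the report. For the unlisted members of a gene list no p-value was used here, so counts adjusted over the list alone could not be computed. Loci that share reads with near-identical copies (histones, tubulins, extensins, LHCB1 genes) are uncertain. The table joins several gene names in 75 entries of potent and 39 of arf7, and the protocol named does not mark strand, so overlapping genes are uncertain too.

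Gene names were matched by locus identifier to the reference annotation of assembly TAIR10.1, which gave a name for 30847 loci and none for 277. It was used for names, product descriptions and gene lengths only. No coordinates are printed, because the files name another build; the digit after AT in a locus identifier is its chromosome. Of 27562 protein-coding loci in that annotation, 1462 are not analysed here.

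In all, 27 gene lists with 286 entries were fixed before the data were examined. They cover auxin signalling, lateral root initiation, the cell cycle, hormone and stress responses, and markers of root and shoot cell types. For each list the median log2 ratio, log2((FPKM + 1)/(FPKM + 1)), was taken over members above 0 in at least 1 genotype, and its percentile was found among 10000 random lists of the same size. Each random member was drawn from the 200 loci nearest in mean log2 level. Percentiles between 2.5 and 97.5 are called inside the matched range. They describe these 3 profiles and are not p-values. The pseudocount of 1 understates changes of low genes. On simulated lists among 22315 loci, 4%, 5% and 1% of unshifted lists of 5, 10 and 25 genes fell outside the range. With a log2 shift of 1, 50%, 72% and 95% did. The simulated genes varied independently and with the same spread at every level, so lists whose members move together were not covered.

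Genes were named by a rule fixed in advance: the altered genes ARF7 and IAA18; the 10 highest and 10 lowest by log2 fold change in each mutant with at least 5 FPKM in a group and neither value at 0; list members in the authors' table, and up to 4 abundant ones outside it (the result of 1 gene is not reported here); and the 5 per direction with the largest change shared by both mutants. For potent against arf7 there is no deposited comparison, so 5 genes per direction were ranked among loci listed in either mutant and above 0 in both. For the overlap, the number of loci listed in both was set beside the number for independent lists among the 19772 loci at or above the lowest level of any listed pair. Chance overlap from the shared controls could not be simulated without values per sample.

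Alternatives were a pseudocount of 0.1, median-ratio scaling, loci filtered at 1 or 5 FPKM, a log2 fold of at least 1 and a q of at most 0.01. Chosen after seeing the data were the lowest q alone, loci without a 0, single-name protein-coding loci, random lists of protein-coding loci or matched on gene length, and members without a 0. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.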

Results

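RNA was profiled in the oscillation zone of the Arabidopsis root, the region behind the tip in which auxin response rises and falls periodically and sites of future lateral roots are set. Control (Col0) samples were collected when the DR5::Luciferase signal, a reporter of auxin response, was at its minimum. They were compared with potent, a line altered in the auxin response repressor IAA18, and with arf7, a line altered in the auxin response factor ARF7. Each group had 3 independent samples. The labels do not state the phase of the mutant samples, so genotype and phase are not separated. The deposited table gives 1 FPKM value per locus and genotype, without the spread between samples, and the depth is unknown. At least 1 FPKM was reached by 15957 loci in the control, 16603 in potent and 16217 in arf7.

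The altered genes were examined first. ARF7 (AT5G20730) had 12.0 FPKM in the control, 9.35 in potent and 2.64 in arf7, 4.56-fold less in arf7 than in the control. IAA18 (AT1G51950) had 10.6 FPKM in the control, 21.8 in potent and 19.1 in arf7. Neither gene is in the authors' deposited table for either mutant.

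The comparison of potent with control asked which transcripts of the zone differ in the line altered in IAA18. In potent, the lists of root hair, xylem, lateral root initiation and auxin conjugation and transport genes lay above the matched range and that of cell wall remodelling genes below it, though few of the xylem and lateral root initiation genes are listed. Of 8 root hair markers, 5 rose and 1 fell. PRP3 (AT3G62680), a proline-rich wall protein of root hairs, rose from 88.5 to 1120 FPKM and the expansin EXPA18 (AT1G62980) from 53.6 to 430 FPKM, while RHD6 (AT1G66470), a regulator that starts hair development, fell from 32.2 to 6.29 FPKM. The authors' deposited table lists 740 loci as higher and 842 as lower in potent, of which 190 were at 0 in the control and 138 at 0 in potent.

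Of the auxin-related genes, 3 of the 16 for conjugation and transport rose in potent and 3 fell. The genes that rose encode GH3 enzymes, which attach amino acids to auxin: GH3.1 (AT2G14960) rose from 0.536 to 29.5 FPKM, GH3.5 (AT4G27260) from 2.86 to 71.3 FPKM and GH3.6 (AT5G54510) from 2.28 to 26.1 FPKM. The efflux carrier gene PIN2 (AT5G57090) fell from 61.4 to 4.85 FPKM, the influx carrier gene LAX3 (AT1G77690) fell from 126 to 38.9 FPKM, and LAX2 (AT2G21050) fell from 1.21 FPKM and is listed at 0 in potent. The median log2 ratio of this list was 0.88, at percentile 99.44 of matched random lists. Of 27 Aux/IAA repressor genes above 0, IAA13 (AT2G33310) rose from 15.4 to 49.6 FPKM and the others are not listed, with a list median of 0.66 at percentile 99.92. Among 15 ARF genes ARF4 (AT5G60450) rose 9.28-fold from 1.87 FPKM, and the list median of 0.40 lay inside the matched range. None of the 6 auxin receptor genes is listed in potent, and the list median of -0.72 lay inside the matched range at percentile 5.6. The receptor gene with the largest difference, AFB1 (AT4G03190), had 81.0 FPKM in the control and 0.329 in potent.

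Of 21 lateral root initiation genes above 0, 3 rose in potent, 1 fell and 17 are not listed. The median log2 ratio was 1.22, above that of every matched random list. LBD16 (AT2G42430), a direct target of ARF7 needed for founder cell division, rose from 1.92 to 49.0 FPKM. LBD29 (AT3G58190) and LBD33 (AT5G06080), both listed at 0 in the control, rose to 12.1 and 13.3 FPKM. EXPA17 (AT4G01630), an expansin of the tissue overlying primordia, fell from 480 to 123 FPKM. GATA23 (AT5G26930), a factor of founder cell identity, had 4.77 FPKM in the control and 25.3 in potent, and MAKR4 (AT2G39370) had 0.25 and 36.8 FPKM, without being listed. EXPA14 (AT5G56320), also not listed, went the other way, with 36.3 FPKM in the control and 21.6 in potent. Of the 21 genes, 16 lay above the control in potent and 5 below it. Of 25 cell cycle genes 1 rose, the mitotic kinase gene CDKB2;1 (AT1G76540, from 2.39 to 17.8 FPKM), and 1 fell, the cyclin gene CYCA3;2 (AT1G47210, from 23.5 to 1.80 FPKM). The list median was 0.98 at percentile 99.9, but without the 8 members at 0 in some genotype it was 0.47, inside the matched range at percentile 86.12.

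Lists of markers of other root tissues and of shoot tissue lay above or inside the matched range in potent. Few of their members are listed, and none of them as lower. Of 8 xylem markers, 2 rose: XCP1 (AT4G35350), a protease of dying vessel cells, from 42.2 to 261 FPKM, and XCP2 (AT1G20850) from 37.0 to 123 FPKM. The xylem list median was 1.77 at percentile 99.95. No endodermis marker is listed, yet the median of the 8 was 1.33 at percentile 99.88, and the Casparian strip gene CASP1 (AT2G36100) had 1375 FPKM in the control and 4255 in potent. The phosphate exporter gene PHO1 (AT3G23430, in an entry that joins it with a neighbouring gene) rose from 3.72 to 52.4 FPKM, and its list of 3 pericycle and mature stele markers had a median of 3.167 at percentile 99.93. Of 11 green shoot markers 2 rose, among them the photosystem gene PSBO1 (AT5G66570, from 13.3 to 61.2 FPKM), with a median of 1.36 at percentile 99.99. Of 6 root cap markers 3 were above 0 and none is listed, with a median of 3.36 at percentile 99.97. Lists for phloem (median 1.203), early vascular tissue (0.71), meristem and quiescent centre (0.44) and non-hair epidermis (0.00) lay inside the matched range.

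Of 10 nitrate and phosphate genes 4 rose in potent and none fell, with a median of 1.25 at percentile 99.91. They were the nitrate transporter gene NRT1.1 (AT1G12110, from 26.9 to 126 FPKM), the nitrate reductase genes NIA1 (AT1G77760) and NIA2 (AT1G37130), and the phosphate transporter gene PHT1;1 (AT5G43350, from 62.1 to 319 FPKM). Of 10 cell wall remodelling genes, XTH17 (AT1G65310), XTH19 (AT4G30290), EXPA1 (AT1G69530) and EXPA17 fell and XTH20 (AT5G48070) rose, with a median of -0.91 at percentile 0.76. Of these 10, 7 lay below the control and 3 above it. Among the latter was EXPA4 (AT2G39700), which is not listed and had 0.669 FPKM in the control and 83.8 in potent. RD29A (AT5G52310) rose among the 3 abscisic acid response genes, whose median was 1.42 at percentile 98.845 but lay inside the matched range with a pseudocount of 0.1 (percentile 96.985) or without members at 0 (percentile 97.14). The other lists lay inside the matched range in potent: circadian clock (median 0.13), cytokinin response regulators (-0.29), jasmonate (0.42), heat shock (0.12), touch and wounding (0.65), low oxygen (0.02), iron deficiency (0.43) and salicylic acid (3.196, with 1 member above 0). Within them the clock-controlled gene GRP7 (AT2G21660) fell from 858 to 142 FPKM, the response regulator gene ARR3 (AT1G59940) fell from 82.0 to 5.25 FPKM, and HSP70 (AT3G12580), SUS1 (AT5G20830), PDC1 (AT4G33070), JAZ1 (AT1G19180) and JAZ6 (AT1G72450) rose. The jasmonate list moved outside the range with a pseudocount of 0.1, to a median of 1.195 at percentile 99.

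Genes ranked by fold in potent were led among those that fell by AT2G43610, a chitinase family gene (211.6 to 1.01 FPKM), the peroxidase gene PER16 (AT2G18980, 520 to 5.86 FPKM), AT3G50640 (189 to 2.38 FPKM) and LNG1 (AT5G15580, a microtubule-associated regulator of cell elongation, 28.4 to 0.371 FPKM). They were followed by DRT100 (AT3G12610), the endoglucanase family gene GH9B13 (AT4G02290), DFC (AT5G10130), the beta-expansin EXPB1 (AT2G20750), AT1G05660 and sks4 (AT4G22010). Those that rose were led by ATC (AT2G27550), a homologue of the flowering repressor TFL1 (3.66 to 229.9 FPKM), the defensin-like gene AT3G59930 (4.30 to 254 FPKM), AT4G25790 (2.86 to 160.0 FPKM) and GH3.1. The next were the triterpene synthase gene PEN1 (AT4G15340), AT5G10580, CB5-C (AT2G46650), GDU4 (AT2G24762), IGMT3 (AT1G21110) and the xyloglucan-modifying enzyme gene XTH31 (AT3G44990). In the authors' deposited table these 20 genes have log2 fold changes from -7.71 to 5.97, with q of 0.00145 or 0.00269.

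**Figure D1:**
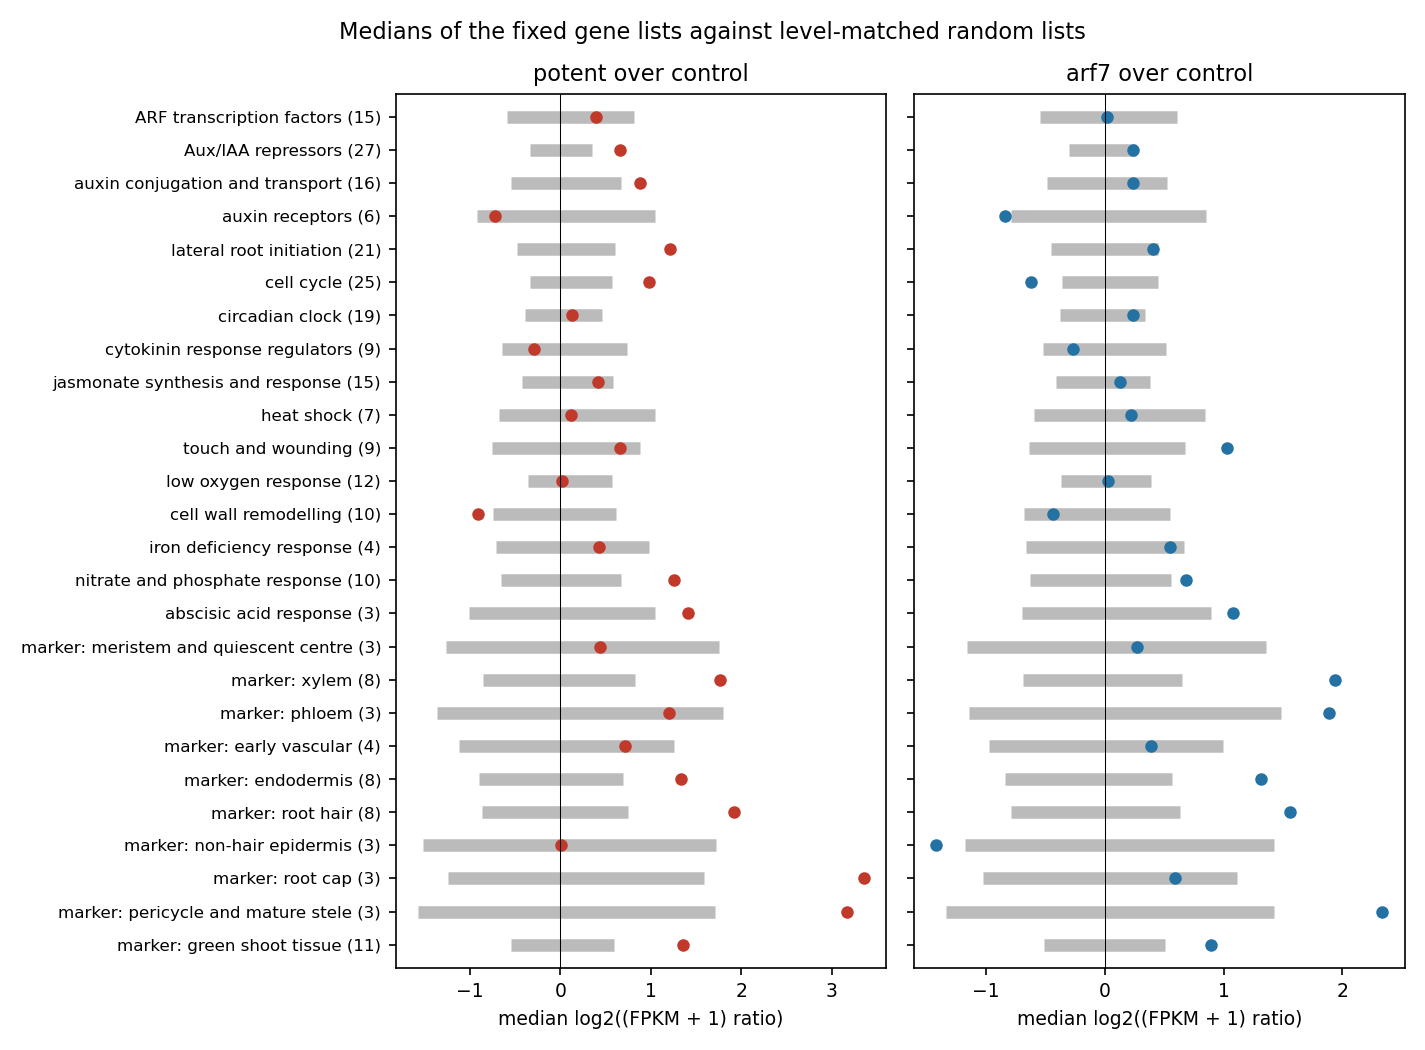
Median log2 ratio, log2((FPKM + 1) ratio), of each fixed gene list in potent (left, red points) and arf7 (right, blue points) against the control; lists with at least 3 members above 0 are drawn and the number of such members is in brackets. Grey bars span percentiles 2.5 to 97.5 of 10000 level-matched random lists. The root hair, xylem, endodermis and pericycle lists lie right of the bar in both panels, while the cell cycle list lies right of it in potent and left of it in arf7.

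The comparison of arf7 with control asked the same of the line altered in ARF7. In arf7, the lists of root hair, xylem and endodermis markers lay above the matched range and none of their members fell, though most members of the xylem and endodermis lists are not listed. Of 8 root hair markers 5 rose: EXPA7 (AT1G12560, from 165 to 401 FPKM), EXPA18 (from 53.6 to 282 FPKM), the wall protein gene LRX1 (AT1G12040), PRP3 (from 88.5 to 433 FPKM) and the actin-depolymerising factor gene ADF8 (AT4G00680). The list median was 1.55, above that of every matched random list. Of 8 xylem markers 3 rose, XCP1 (from 42.2 to 222 FPKM), XCP2 and MYB46 (AT5G12870), a switch of secondary wall formation (from 6.58 to 32.2 FPKM), with a median of 1.94, again above every random list. Among the endodermis markers the Casparian strip gene CASP4 (AT5G06200) rose from 313 to 995 FPKM, and the median of the list was 1.31 at percentile 99.92. The authors' deposited table lists 440 loci as higher and 555 as lower in arf7, of which 96 were at 0 in the control and 66 at 0 in arf7.

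Of 25 cell cycle genes above 0, 3 fell in arf7 and none rose, and 22 had a lower value than in the control. CYCA3;2 fell from 23.5 to 2.14 FPKM, and CYCB1;4 (AT2G26760) and CDC20.1 (AT4G33270), an activator of mitotic exit, fell from 2.48 and 1.06 FPKM and are listed at 0 in arf7. The replication clamp gene PCNA1 (AT1G07370), which is not listed, had 19.6 FPKM in the control and 8.55 in arf7. The list median was -0.62 at percentile 0.04. Of 21 lateral root initiation genes 1 rose, LBD29, which is listed at 0 in the control and had 6.28 FPKM in arf7. LBD16 had 1.92 FPKM in the control and 31.2 in arf7, and is not listed. The list median of 0.40 lay inside the matched range at percentile 96.45, and outside it with a pseudocount of 0.1 (0.80 at percentile 98.92) or with random lists of protein-coding loci (percentile 97.525).

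In the auxin groups of arf7, IAA13 rose from 15.4 to 59.5 FPKM, PIN2 fell from 61.4 to 6.83 FPKM and the receptor gene TIR1 (AT3G62980) fell from 31.6 to 10.2 FPKM. The auxin receptor list, of which 5 of 6 members had lower values than in the control, had a median of -0.84 at percentile 1.97. The Aux/IAA list had a median of 0.24 at percentile 96.67, inside the matched range, and 0.61 at percentile 99.77 without members at 0. The conjugation and transport list (0.24) and the ARF list (0.02) were inside it, and no ARF gene is listed.

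Among the other lists in arf7, NRT1.1 rose from 26.9 to 111 FPKM, the only listed member of the nitrate and phosphate group (median 0.68, percentile 98.92), and PHO1 rose from 3.72 to 43.5 FPKM in the pericycle and mature stele group (median 2.34, percentile 99.75). RD29A rose from 6.74 to 55.3 FPKM, with an abscisic acid list median of 1.08 at percentile 98.225 that lay inside the range with a pseudocount of 0.1 (percentile 93.24). No member of the touch and wounding list is listed, and its median was 1.03 at percentile 99.76. The green shoot markers had a median of 0.90 at percentile 99.93 and the 3 phloem markers 1.89 at percentile 99.355, with no listed member. The non-hair epidermis list, 3 genes, had a median of -1.42 at percentile 0.965; WER (AT5G14750), a regulator of hairless cell fate, had 12.8 FPKM in the control and 0.648 in arf7. Inside the range were cell wall remodelling (-0.44), clock (0.24), cytokinin (-0.27), jasmonate (0.13), heat shock (0.22), low oxygen (0.03), iron deficiency (0.55), salicylic acid (2.23), early vascular (0.39), meristem (0.28) and root cap (0.59). The root cap list moved outside it with a pseudocount of 0.1 (2.37, percentile 99.125) or without members at 0 (1.94, percentile 98.695). GRP7 fell from 858 to 129 FPKM, ARR3 from 82.0 to 11.1 FPKM and EXPA1 from 49.4 to 11.9 FPKM, HSP70 and SUS1 rose, LOX4 (AT1G72520) rose from a listed 0 to 0.752 FPKM, and JAZ10 (AT5G13220) fell from 1.39 FPKM and is listed at 0.

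Ranked by fold, the genes that fell in arf7 were led by AT2G43610 (211.6 to 3.61 FPKM), BS1 (AT1G74500), a helix-loop-helix regulator of growth (154 to 3.06 FPKM), the arabinogalactan protein gene AGP30 (AT2G33790, 535 to 15.2 FPKM) and AT1G54890 (96.1 to 2.79 FPKM). They were followed by the histone gene HTR1 (AT5G10400), AT5G12940, UNE11 (AT4G00080), AT5G66590, BZIP61 (AT3G58120) and PDF2.5 (AT5G63660). The genes that rose were led by IGMT3, an indole glucosinolate methyltransferase family gene (1.24 to 44.5 FPKM), AT5G10580 (2.55 to 91.2 FPKM), the amino acid exporter family gene UMAMIT27 (AT1G11450, 1.39 to 34.0 FPKM) and BGAL4 (AT5G56870, 2.40 to 47.6 FPKM). After them came AT5G07080, BAT1 (AT4G31910), a brassinosteroid-inactivating acyltransferase, the amino acid permease gene AAP2 (AT5G09220), CYP71A27 (AT4G20240), ATL80 (AT1G20823) and UMAMIT28 (AT1G01070). Log2 fold changes of these 20 genes in the authors' deposited table run from -5.87 to 5.16, with q from 0.00145 to 0.00945.

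**Figure D2:**
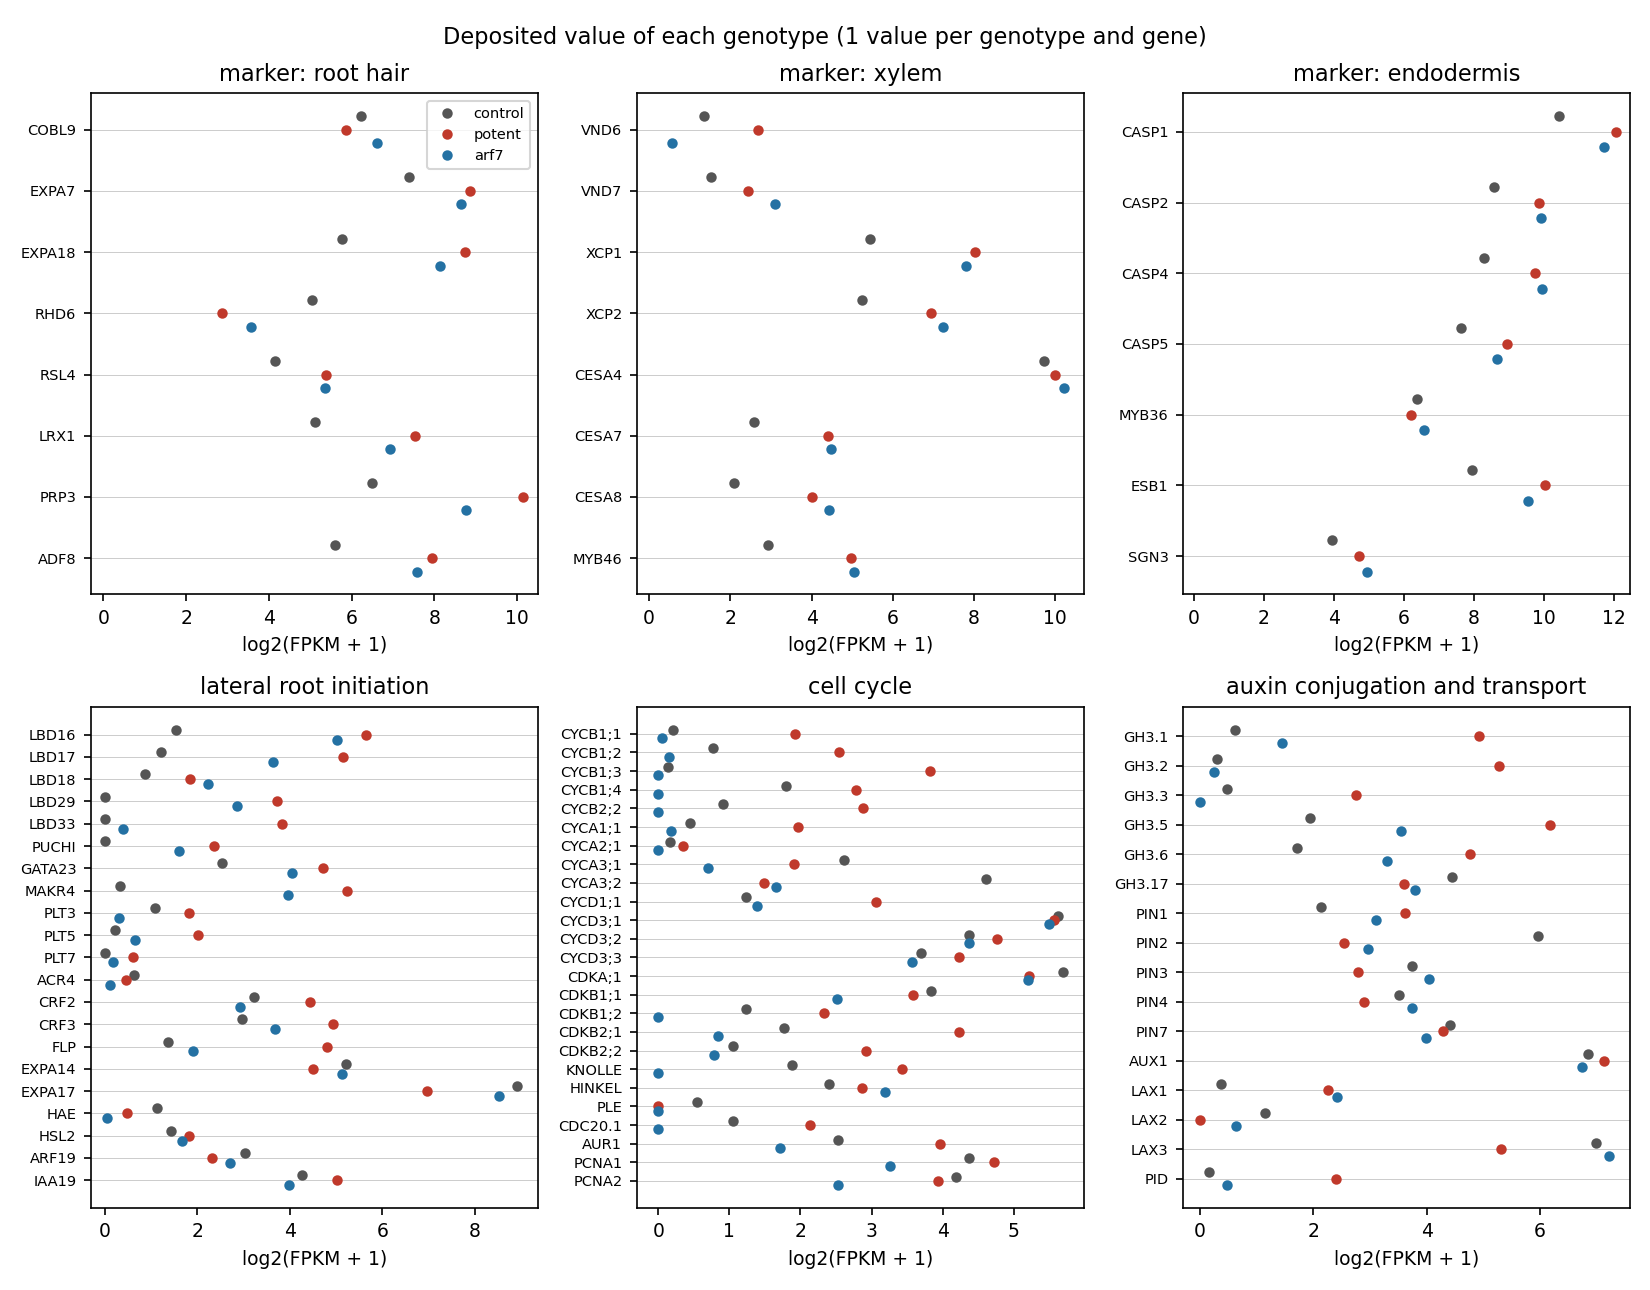
Deposited value, log2(FPKM + 1), of genes from 6 of the fixed lists in control (grey), potent (red) and arf7 (blue); each point is the authors' single value for a genotype, so no error is drawn. PRP3 stands at 88.5, 1120 and 433 FPKM in control, potent and arf7, and CDKB2;1 at 2.39, 17.8 and 0.783 FPKM.

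Both mutants were then compared for the genes they share. Loci listed as higher in both numbered 289, or 65.7% of the arf7 and 39.1% of the potent loci that rose, where independent lists would share 16.5. Loci listed as lower in both numbered 360, where independent lists would share 23.6. A single locus, AT5G17160, is listed in opposite directions. Both comparisons use the same control samples, so part of the excess may come from these, and the controls could not be split. The number for independent lists also takes all 19772 loci as equally likely to be listed. Of the listed loci, however, 1346 of 1582 in potent and 850 of 995 in arf7 had at least 5 FPKM in a group. Part of the excess may come from this too. Among loci listed in both mutants, the largest shared increases were those of IGMT3, AT5G10580, UMAMIT27, BGAL4 and AT5G07080. Among the same loci, the largest shared decreases were those of AT2G43610, BZIP61, AT3G50640, HTR1 and XPL1 (AT3G18000). XPL1, a phosphoethanolamine methyltransferase of phosphocholine synthesis, fell from 220 FPKM to 9.73 in potent and 9.05 in arf7. Some loci with larger differences in both mutants are listed as lower in arf7 alone, and so are not among the 360. AGP30 had 535 FPKM in the control, 0.104 in potent and 15.2 in arf7, and BS1 had 154, 0.0985 and 3.06 FPKM. Potent was farther from the control than arf7 for 209 of the 289 shared higher loci and 258 of the 360 shared lower loci. Of 450 loci listed as higher in potent alone, 401 also lay above the control in arf7, with medians of 1.99 in potent and 1.02 in arf7 on the log2 scale. Of 482 listed as lower in potent alone, 466 also lay below the control in arf7. Conversely, 141 of 151 loci listed as higher in arf7 alone lay above the control in potent, with medians of 1.64 in arf7 and 1.02 in potent. Below the control in potent lay 181 of the 194 listed as lower in arf7 alone. Loci listed in a single mutant are picked for their values there, so these medians do not compare the sizes of the responses. Both mutants are also set against the same control value, so an error in that value alone would put both on the same side. The share over all loci is not given, so the counts on the same side do not measure a shared response.

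**Figure D3:**
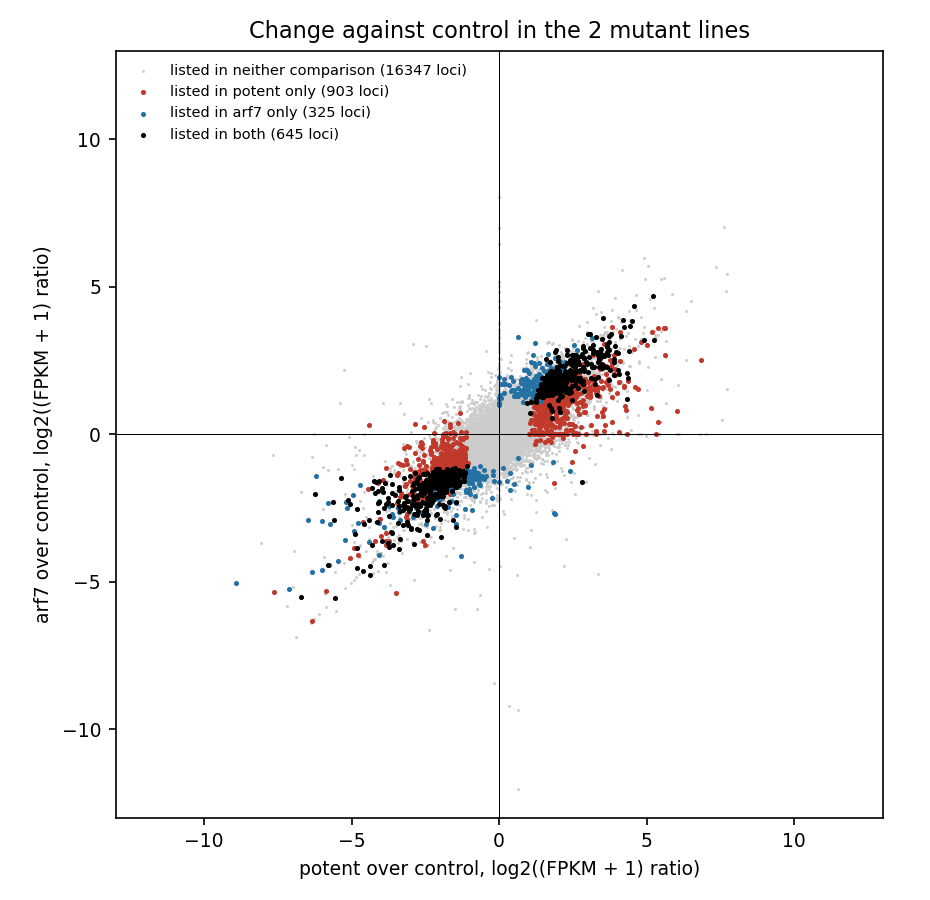
Log2((FPKM + 1) ratio) of arf7 over control (vertical) against potent over control (horizontal); each point is 1 of the loci with at least 1 FPKM in some genotype, coloured by whether the authors' deposited table lists it in both comparisons (black), potent (red), arf7 (blue) or neither (grey). Points listed in both lie in the lower left and upper right corners, except AT5G17160.

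The mutants were last set against each other, for which there is no deposited comparison and no test here. Lateral root initiation and cell cycle genes stood higher in potent than in arf7. The lateral root initiation list had a median log2 ratio of potent over arf7 of 0.75 and the cell cycle list of 1.67, both above every matched random list. FLP (AT1G14350), a regulator of formative divisions, had 27.1 FPKM in potent and 2.74 in arf7, and AUR1 (AT4G32830), an Aurora kinase gene, had 14.7 and 2.27 FPKM. Lateral root initiation genes that went the other way include EXPA17 (123 FPKM in potent and 367 in arf7) and EXPA14 (21.6 and 33.7 FPKM). The nitrate and phosphate list (0.51, percentile 98.86) and the green shoot list (0.68, percentile 99.845) also stood higher in potent. Auxin receptors (-0.56, percentile 1.79) and cell wall remodelling genes (-0.39, percentile 2.1, or 2.53 with a pseudocount of 0.1) stood lower. The other 21 lists lay inside the matched range, including root hair, xylem and endodermis markers, although auxin conjugation and transport (0.34) lay above it with random lists matched on gene length (percentile 98.62) and root cap (0.06) without members at 0 (1.90, percentile 98.365). Among listed loci, the largest ratios of potent over arf7 were those of AT4G16008, AT3G60670, AT5G44570, AT4G00130 and IMS2 (AT5G23020, 40.4 against 0.342 FPKM), all listed at 0 in the control. The smallest were those of OCT3 (AT1G16390), AGP30 (0.104 against 15.2 FPKM), AT3G24750, PMEI4 (AT4G25250) and EXPA11 (AT1G20190, 0.745 against 19.5 FPKM).

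The authors' deposited table leaves out some of the largest differences. Over both mutants together, no protein-coding pair with a lower value above 0 and up to 0.3 FPKM and a higher value of at least 5 FPKM is listed (0 of 236). Of 154 pairs with a lower value of exactly 0, 67.5% are listed (73.3% of 120 in potent and 47.1% of 34 in arf7). AGP30 (535 FPKM in the control, 0.104 in potent), BS1 (154 and 0.0985 FPKM) and AT1G54890 (96.1 and 0.204 FPKM) are among those left out in potent.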

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

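The tests of explanations in this part were all chosen after the results were seen. AT5G17160, in an entry joined with AT5G17150, is the only locus that the authors' deposited table lists in opposite directions, with 2.04 FPKM in the control, 20.5 in potent and a listed 0 in arf7; the difference between the mutants was not tested.

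The cell cycle list stood above the control in potent and below it in arf7, a difference of 1.67 (median log2 ratio of potent over arf7) that was not tested, since there is 1 value per genotype. Failed estimates, listed at 0 in arf7, are not the whole of the decrease in arf7: over the 17 members above 0 in all genotypes the median of arf7 over control was -0.50 (percentile 1.73), with 14 of 17 below the control. The increase in potent over control is less secure, since over these members its median of 0.47 was at percentile 85.865, while potent over arf7 stayed at 1.40, above every matched random list. A candidate explanation is more lateral root founder or primordium cells in the potent piece than in the arf7 piece: the lateral root initiation list, of which 13 of 21 members also have at least 1 FPKM in the control, had a median of 0.75 in potent over arf7, above every matched random list, and its most abundant members in potent were EXPA17 (123 FPKM against 367 in arf7), LBD16 (49.0 against 31.2) and MAKR4 (36.8 against 14.5). However, the green shoot (0.68) and the nitrate and phosphate (0.51) lists, which do not mark these cells, also stood higher in potent than in arf7, and an effect of either genotype on the cell cycle itself, or a different oscillation phase of the samples, stays open and was not tested.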

How the results depend on the processing

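Of 45 alternative values that could move the numbers of listed loci and their overlap, 41 stayed within 1.5 times, as did all 12 for the numbers of gene lists outside the matched range, and the 4 that did not came from keeping only the lowest q, an alternative chosen after seeing the data, as were all those on loci or members at 0, single-name protein-coding loci, protein-coding random lists and gene length. That limit left 650 of 995 loci in arf7 (278 of 440 higher) and 428 loci shared by both mutants in the same direction (185 of 289 higher); the stricter limit itself removes these loci. Limits of 0.05 or 0.01 on q, or of 1 on the log2 fold, remove no listed locus and so test nothing. Of 324 values of single lists under the alternatives other than median-ratio scaling, 307 kept their direction and side of the matched range, 8 moved outside it, 5 moved inside it and 4 changed sign. The sign changes were all in potent over arf7 and inside the matched range: low oxygen (0.16), abscisic acid (-0.11) and pericycle and mature stele (-0.49) without members at 0, and iron deficiency (0.0712) with a pseudocount of 0.1. The cause was not tested. Median-ratio scaling shifted all log2 ratios by 0.01 in each mutant, too little to test stability, and for single genes a pseudocount of 0.1 can change no sign and so tests nothing. No paired analysis was possible because the deposited tables hold 1 value per genotype and no column for any replicate. For the same reason quantile normalization, leaving out each replicate, limma, DESeq2, camera, fry, a split of the controls, a test of potent against arf7 and a simulation of the shared controls were not run. The depth of the samples is unknown, and the spread between samples enters only through the authors' q.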

Other observations

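The tests in this part, and the gene families grouped by product name, were chosen after the results were seen. Of 12 protein disulfide isomerase-like genes 8 fell in potent and 8 in arf7, among them PDIL1-1 (AT1G21750), from 814 FPKM to 116 in potent and 183 in arf7. Of 10 genes for coatomer, the coat of Golgi vesicles, 8 fell in potent and 7 in arf7. Core histones fell for 12 of 39 genes in potent and 14 in arf7, tubulins for 9 of 15 and 7, and subunits of the TCP-1 chaperonin, which folds tubulin and actin, for 4 of 9 and 6. The medians of these 5 families lay below the matched range in both mutants, from -1.89 to -1.23 on the log2 scale in potent and from -1.85 to -0.92 in arf7. In contrast, 8 of 13 proline-rich extensin-like genes rose in each mutant (medians 3.16 and 2.19). EXT13 (AT5G35190) rose from 51.3 FPKM to 546 and 300.1. Of 62 genes grouped as class III peroxidases by product name, 14 rose in potent and 10 in arf7, where matched random lists had means of 2.74 and 1.92. The 14 include DOX1 (AT3G01420), a dioxygenase gene outside that class. In potent 6 fell and in arf7 2, at percentiles 93.8 and 42.01 of the random lists. The medians of 0.59 and 0.56 lay above every random list. Of 7 glutamine dumper genes, regulators of amino acid export, 5 rose in potent and 1 in arf7. Of 52 arabinogalactan protein genes 2 rose and 11 fell in potent and 3 rose and 4 fell in arf7, with medians of -0.47 and 0.01. Of 23 expansin genes 2 rose and 4 fell in each mutant. Members of these families share reads to an unknown degree.

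The next 5 genes of methionine-derived glucosinolate synthesis were picked because their values were near 0 in the control; other genes of the pathway are left out, so nothing is said of the pathway as a whole. IMS2 (AT5G23020, named MAM3 in the authors' deposited table) and IPMI2 (AT2G43100) are listed at 0 in the control and rose in potent to 40.4 and 37.1 FPKM, and IPMI2 rose in arf7 to 8.17 FPKM. IPMI1 (AT3G58990) had 0.428 FPKM in the control, 129.9 in potent and 32.1 in arf7. CYP79F2 (AT1G16400) had 0.0221, 38.5 and 9.17 FPKM, and IMD1 (AT5G14200) had 0.754, 57.5 and 7.51 FPKM, without being listed.

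Markers of mature tissue were higher and ribosomal proteins lower in both mutants: 27 pooled markers of root hair, xylem, endodermis and mature stele had medians of 1.49 in potent (8 higher, 1 lower and 18 not listed) and 1.60 in arf7 (11 higher and 16 not listed), and 285 genes grouped by product names of ribosomal proteins, in which those of organelles were not fully separated, had -0.73 and -0.97, with 6 listed as lower and 1 as higher in potent, where matched random lists had means of 20.9 and 18.6, and 58 as lower and none as higher in arf7, where they had 17.3 and 13.9; 70 of the 285 lay above the control in potent and 41 in arf7. A scaling difference between genotypes would move both sets alike, and the smaller gap between their medians was 2.22. Both sets were put together after their directions were seen, so this gap restates the pattern and is not a separate test. Gene length bias is argued against by random lists matched on length as well as level, among which the markers lay at percentile 100 and the ribosomal proteins at 0 in both mutants. Older tissue in the dissected piece of the mutants would lower the cell cycle list in both. The median of that list was 0.98 in potent (0.47, inside the matched range, over the 17 members above 0 in all genotypes) and -0.62 in arf7. Core histones lay below the matched range in both mutants, with medians of -1.55 in potent (34 of 39 below the control) and -1.85 in arf7 (37 of 39). The cell cycle list alone therefore does not decide this, and the marker lists are the pattern itself and give no test. Older tissue, earlier differentiation caused by either genotype and the oscillation phase therefore cannot be told apart here.

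Large changes are often absent from the authors' list. A higher value under 20 FPKM does not account for this. Pairs of a control and a mutant value were taken, above 0 in both and with at least 20 FPKM in 1 of them. Of 89 such pairs with a change above 6 on the log2 scale, 4.49% are in the authors' deposited table, against 61.2% of 1393 with a change of 2 to 4. The limit of 20 FPKM holds for the higher value only, so a low level of the lower value is not excluded. A candidate explanation is that the authors' test rarely calls a pair whose lower value is close to 0 but not 0: among protein-coding pairs with a log2 change of 4 to 6 and a higher value of at least 20 FPKM, 8.33% of 48 with a lower value up to 1 FPKM are in the authors' deposited table, against 61.7% of 154 with a lower value above 1. Other folds were not compared in this way. The higher values of these pairs differ too (medians 24.9 and 67.0 FPKM in potent, 23.7 and 55.1 in arf7), so the level of the pair was not held equal. Pairs with a lower value of exactly 0 are an exception (67.5% of 154 listed, both mutants together). They were taken with a higher value of at least 5 FPKM and have no fold, so their share is not directly comparable with the 2 above. With the same limit of 5 FPKM, 0 of 236 pairs with a lower value above 0 and up to 0.3 FPKM are listed. What the test or a later filter did with such pairs is not given in the sources used here, and no biological explanation was tested.

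The 9 distinct q-values of the authors' deposited table all match Benjamini-Hochberg adjustment over 184920 tests with p-values in steps of 5e-05; the next best number of tests up to 250000 matched 6. On simulated tables, whose numbers of tests all lay within the searched range, the number was recovered in 20 of 20 runs. The q-values fix the number only up to a common multiple, so 184920 is the smallest match and its multiples were not searched. With 184920 tests there would be 8806 calls at the largest q, of which 2577 are in the table, and a multiple would give more. For all loci, 3 comparisons would make 93372 tests. Which comparisons the tests covered is not given in the sources used here, so the calls outside the table cannot be assigned to either mutant.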
